A study of Mus musculus with 20 samples.

How the data were processed

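RNA-seq was measured in 20 libraries from cultured forebrain slices of mouse pups at postnatal day 4, exposed to 5% horse serum for 4 h or 24 h. The libraries were made from total RNA with SMART-Seq chemistry, per the labels' protocols. At 4 h there were 3 wild-type (WT) libraries and 3 libraries labelled knockout (KO) for Tnfaip6, the gene of the hyaluronan-binding protein TSG-6. At 24 h there were 3 heterozygous (Het) and 4 KO-labelled libraries of each sex. The 24 h treatment text speaks of WT slices, whereas sample titles and genotype fields say heterozygous; the titles were followed. The series text names HBSS as the serum medium and the sample protocols name DMEM. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which could be technical. Slices without serum were not analysed here.

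The submitters' processing notes name TopHat2, HTSeq, DESeq2 1.38.3 and the genome build GRCm38 (mm10), without saying which step each served; the versions of TopHat2 and HTSeq, the annotation release and the strand setting are not given in the sources used here. The 24 h table deposited by the authors holds raw read counts, whole numbers for 51912 gene identifiers, of which 21642 were 0 in every library. The 4 h table deposited by the authors holds a signal that is not whole: read counts of 19722 genes divided by one size factor per library. Whole reads were recovered from it by dividing each column by the worth of 1 read, and 100% of values came out whole within a tolerance of 0.05. The 6 factors equal the median-of-ratios factors of these reads to within 5.82e-10. No gene of the 4 h table was 0 in all libraries, the smallest total being 2 reads, so it had been filtered before deposit. Ensembl identifiers were matched to gene symbols with the supplied reference table, for 19673 of the 4 h and 51633 of the 24 h identifiers. Identifiers without a symbol held 0.0462% of the reads at 4 h and 0.0396% at 24 h and stayed in the tests. Coordinates are those of GENCODE annotation of GRCm38, 1-based. Since the strand setting is not given, reads from overlapping genes on opposite strands cannot be told apart.

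Library totals were 11411532 to 15030171 recovered reads at 4 h and 8482933 to 18051300 counts at 24 h, and the 50 most abundant genes took 8.02% to 10.0% of them. Replicates were compared by a chi-square test of their counts over genes. The statistic per degree of freedom lay between 3.32 and 13.6 for pairs within a group and between 3.32 and 14.4 for the 82 pairs from different groups of a table, so no pair compared within a table agreed within sampling noise. Where a gene had 0 reads, the upper limit is that of 3 counts; such limits cover counting error only, since PCR copies are not independent molecules.

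For the 24 h table, edgeR 4.0.16 under R 4.3.3 was used with TMM scaling, its default expression filter (16013 genes kept) and its quasi-likelihood F test, two-sided, with 1 mean per genotype and sex over all 14 libraries. Contrasts were KO minus Het in females, in males and averaged over sexes, the difference between the male and female contrasts, and males minus females. The design fixed edgeR for the 4 h table as well. As that table turned out not to hold counts, limma 3.58.1 with an intensity trend was used on log2(value + 1) for the 15181 genes with a mean value of at least 10. A fold change at 4 h is therefore on the log2(value + pseudocount) scale, which understates changes of low genes. The edgeR test on the recovered reads was run as an alternative. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, from limma at 4 h and edgeR at 24 h unless another tool is named. Fold changes are given with their standard errors (SE), group values with the SD; 24 h levels are CPM, counts scaled to a common library total. The tables were fitted separately because they differ in time, control genotype and gene set.

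Gene lists (32 lists, 672 genes) were written before the data were examined, as were the comparisons, their tests, most alternative settings and the rule for naming genes. They cover hyaluronan binding and turnover, collagens and matrix glycoproteins, matrix proteases, immediate early genes, proinflammatory and interferon genes, TGF-beta and SRF targets, hypoxia, unfolded protein and heat shock genes, cell cycle, apoptosis, ribosomal and mitochondrially encoded genes, pan-reactive, A1 and A2 astrocyte genes, and markers of astrocytes, oligodendrocyte precursors, myelin, microglia, excitatory and inhibitory neurons, all neurons, striatum, thalamus, hippocampus, endothelium and pericytes, meninges, choroid plexus and ependyma, and erythroid cells. Genes flanking Tnfaip6 on chromosome 2 and sex-linked genes served as label checks. Some genes stand in more than 1 list: Dcn, Lum, Col1a1, Col1a2 and Col3a1 are both matrix and meningeal genes, and Cxcl10, Ptx3, Timp1 and Ptgs2 are shared by inflammatory, astrocyte or matrix lists. Each list was tested with camera at a preset correlation of 0.01, two-sided, and adjusted over the 32 lists of a comparison. Estimated correlations and fry, which tests a list without comparing it with other genes, were the alternatives. A list score is the mean over members of the log2 value minus that gene's mean over the libraries of its table; group differences in scores and in Tnfaip6 were tested by two-sided exact permutation. At 3 against 3 libraries such a test cannot go below 0.1.

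Named genes are Tnfaip6; the 10 largest rises and falls past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out unnamed genes; where none passed, the 5 with the smallest p; up to 4 members with the smallest p of each list described; and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Others are said to be chosen after their values were seen. Single-gene results of a few genes that met these rules are not reported here.

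Replicate numbers are shared between groups. At 4 h the deviations of same-numbered libraries from their group means correlated at 0.264, 0.140 and 0.175 across genes, which met the rule, set beforehand, of over 0.1 for every pair, so the numbers were taken to pair the 4 h libraries and blocked values stand beside results they change. The labels state no pairing. Without 6 sex-linked genes the correlations were 0.0556, 0.0849 and 0.120, so part of the pairing came from sex. The first and second then no longer met the rule of over 0.1. Pairs of unlike number lay between -0.163 and 0.0660, and WT 2 with KO 1 was above WT 1 with KO 1. The pairing, and with it every blocked value at 4 h, is therefore uncertain. The tests were checked on simulated data with known changed genes. Of genes changed 1.5-fold, 64.2% were recovered at 4 h (15077 genes simulated), and 61.2% in females, 74.6% in males and 86.6% in the average at 24 h (15855 genes simulated). Of genes changed 2-fold, 92.5%, 92.5%, 91.0% and 100% were recovered. The changed genes all had a mean log2 CPM of at least 1. Simulated counts varied independently between genes, and no differences in tissue or sex between libraries were simulated. These shares therefore do not rule out changes of that size in the real libraries.

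Alternatives were other scaling, other expression filters, DESeq2 1.42.0, limma-voom with quality weights, robust spread, a minimum fold change, other pseudocounts, leaving out each library, the replicate block, fits within 1 sex, and fits without libraries that stood apart. Their effects close the text.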

Results

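Tnfaip6 encodes TSG-6, a secreted protein that binds hyaluronan and transfers heavy chains of inter-alpha-inhibitor to it during inflammation. The series title places it in matrix changes and hypoxic-ischemic brain injury. Forebrain slices from pups at postnatal day 4 were exposed to 5% horse serum. At 4 h, 3 WT libraries held 14465608, 13173416 and 12473940 reads. The 3 KO-labelled libraries held 11998879, 15030171 and 11411532 reads. At 24 h, 3 Het and 4 KO-labelled libraries of each sex held between 8482933 (KO male 2) and 18051300 counts (KO female 3). The control at 4 h was WT and at 24 h Het.

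The targeted gene was read in every library. Tnfaip6 (ENSMUSG00000053475) lies on chromosome 2 at 52038009 to 52056686, plus strand, and no annotated gene overlaps it. At 4 h its normalised read count was 81.4 ± 13.0 in WT and 65.7 ± 22.3 in KO-labelled slices (SD, n = 3 each), from 37 to 94 reads per library. The log2 fold change was -0.36 ± 0.25 (SE), and the groups did not differ by limma (adjusted p = 0.563) or by an exact permutation test (p = 0.4, 20 arrangements, smallest possible 0.1). At 24 h the level was 4.60 ± 1.08 CPM in Het females (n = 3), 6.51 ± 1.52 in KO-labelled females (n = 4), 5.16 ± 1.24 in Het males (n = 3) and 6.70 ± 0.93 in KO-labelled males (n = 4). The averaged log2 fold change was 0.45 ± 0.16, with an edgeR adjusted p of 0.738. The exact permutation test of this single gene gave p = 0.0204 over 1225 arrangements, higher in KO-labelled slices. The log2 fold change was 0.50 ± 0.22 in females (exact permutation p = 0.171) and 0.39 ± 0.23 in males (exact permutation p = 0.143). The reads do not show the KO label as a loss of transcript. The labels do not say which part of the gene was deleted, and a deletion that leaves most of the transcript would go unseen in these gene totals. Libraries are called KO-labelled for this reason, and every genotype direction here rests on the labels. The genes flanking Tnfaip6 on chromosome 2 had a median log2 fold change of 0.06 at 4 h (20 of 26 above 0, adjusted p = 0.0766, and 0.0388 without KO 1) and 0.02 at 24 h (15 of 26 above 0, adjusted p = 0.71).

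**Figure D1:**
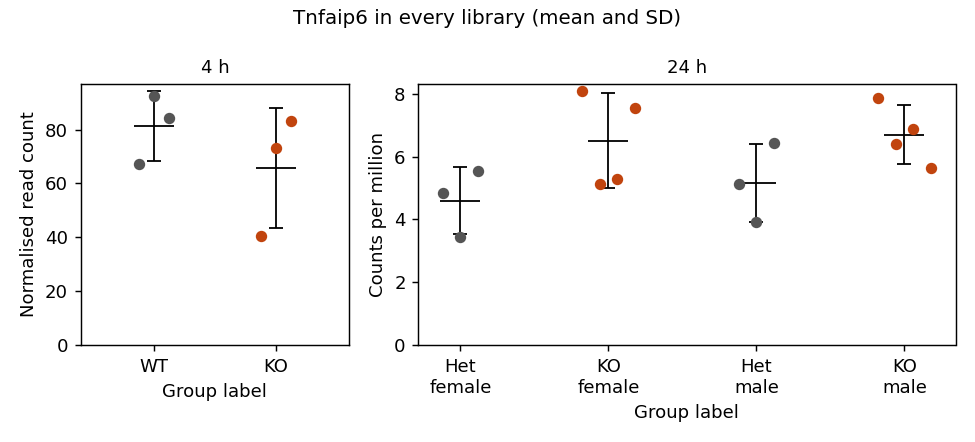
Tnfaip6 per library, as normalised read count at 4 h (left) and CPM at 24 h (right), by group label; points are libraries, horizontal bars the mean and error bars the SD (n = 3 or 4). KO-labelled libraries overlap the controls at 4 h, and no KO-labelled library is near 0.

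The first comparison asks how KO-labelled slices differed from WT slices after 4 h of serum. Fos, Nr4a1 and Egr1, transcription factors that cells switch on within minutes of stimulation, were lower in KO-labelled slices. Fos fell from 3561 ± 531 to 2033 ± 289 normalised reads (SD, n = 3 each), Nr4a1, an orphan nuclear receptor, from 1954 ± 368 to 1049 ± 66.6, and Egr1 from 2109 ± 102 to 1502 ± 54.8. Ccn1, a serum-induced matricellular protein that binds integrins, fell from 800 ± 117 to 450 ± 28.4, and Clk1, a kinase of splicing factors, from 920 ± 54.0 to 615 ± 67.7. Wdfy1, an endosomal adaptor of Toll-like receptor signalling, rose from 265 ± 30.5 to 618 ± 26.1, and Stum, a membrane protein related to a fly mechanosensory factor, from 1553 ± 66.2 to 2161 ± 50.9. These 7 genes were the ones past the threshold among 15181 tested. None had overlapping groups, which chance gives for 10% of unselected genes at this size. Selection by a small p largely brings this with it, so it adds no separate support.

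The log2 fold changes were 1.23 ± 0.10 (SE; limma adjusted p = 0.000174) for Wdfy1, 0.48 ± 0.07 (0.0161) for Stum, -0.88 ± 0.11 (0.0128) for Nr4a1, -0.82 ± 0.11 (0.0128) for Ccn1, -0.81 ± 0.11 (0.0161) for Fos, -0.58 ± 0.09 (0.0448) for Clk1 and -0.49 ± 0.07 (0.0161) for Egr1. In GRCm38, Wdfy1 (ENSMUSG00000073643) lies on chromosome 1 at 79702262 to 79776143, minus strand, where Mrpl44 and Gm10555 overlap it on the opposite strand. Mrpl44 itself had a log2 fold change of 0.10. Fos (ENSMUSG00000021250) lies on chromosome 12 at 85473890 to 85477273, Nr4a1 (ENSMUSG00000023034) on chromosome 15 at 101254269 to 101274795, Egr1 (ENSMUSG00000038418) on chromosome 18 at 34859823 to 34864984, Ccn1 (ENSMUSG00000028195) on chromosome 3 at 145646976 to 145649981, Clk1 (ENSMUSG00000026034) on chromosome 1 at 58410189 to 58424066 and Stum (ENSMUSG00000053963) on chromosome 1 at 180432387 to 180483504. At an unadjusted p under 0.05 there were 2110 genes, against 759 by chance. DESeq2 on the recovered reads called 144 genes, 83 higher and 61 lower. Wdfy1 passed without any 1 library. Without WT 1 the other 6 did not (adjusted p = 0.116 to 0.303), and without WT 2 only Ccn1 of them did. Without WT 3, Stum, Ccn1, Clk1 and Egr1 did not pass (0.0573 to 0.0771), and without KO 3, Stum, Clk1 and Egr1 did not (0.0554 to 0.0710). All 7 passed without KO 1 or KO 2, among 11 and 211 genes.

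**Figure D2:**
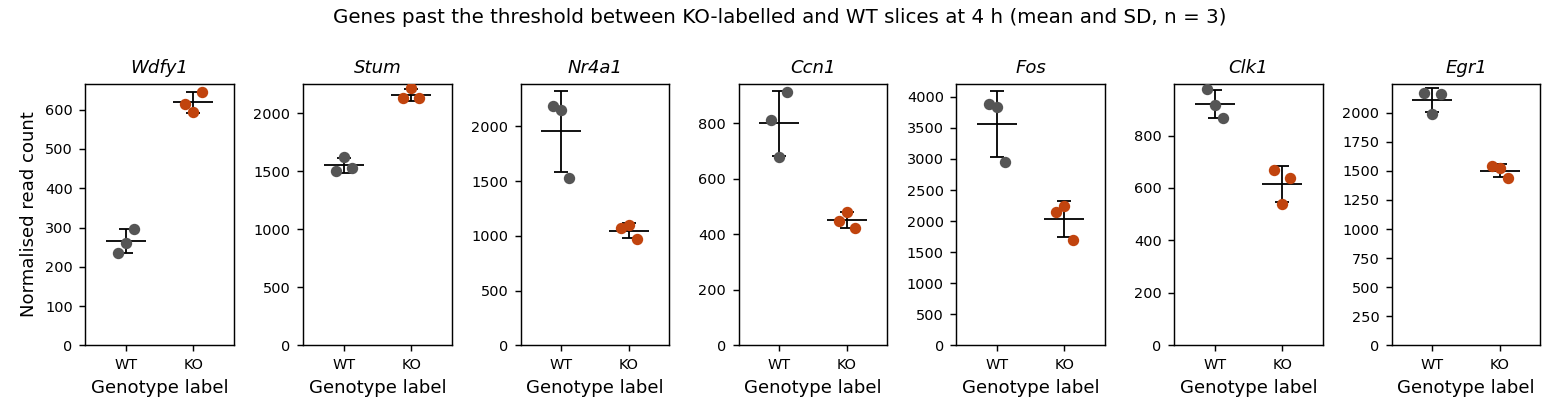
Normalised read counts of the 7 genes past the threshold at 4 h in WT and KO-labelled slices; points are libraries, horizontal bars the mean and error bars the SD (n = 3), and each axis starts at 0. Wdfy1 and Stum are higher and Nr4a1, Ccn1, Fos, Clk1 and Egr1 lower in all KO-labelled libraries.

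With the replicate number as a block, 38 genes passed at 4 h, 11 higher and 27 lower, including the 7 above. Named here after their values were seen, further transcription factors of the immediate early kind were lower under the block: Npas4 (log2 fold change -0.99, blocked limma adjusted p = 0.000202), Fosb (-1.01, 0.000295), Junb (-0.71, 0.00241) and Nr4a3 (-0.58, 0.00867). Also lower were 3 long noncoding RNAs, Malat1 (-0.83, 0.00352), Miat (-0.60, 0.0154) and Firre (-0.75, 0.0269). So were Prelp (-1.06, 0.0390), a proteoglycan of connective tissue, Flna (-0.41, 0.0279), an actin crosslinker, and Hspa1b (-0.94, 0.0451), a heat shock protein. Genes higher under the block included Slc17a7 (0.45, 0.0337), the vesicular glutamate transporter of cortical neurons, Tbr1 (0.46, 0.0451), a factor of deep-layer cortical neurons, Map1a (0.37, 0.0337), a microtubule-associated protein, and Grik3 (0.38, 0.0451), a kainate receptor subunit. Without the block and with no other change, the limma adjusted p of the genes named in this paragraph was 0.0865 (Prelp) to 0.301 (Hspa1b). Some passed under other settings without the block: Prelp (0.0462), Tbr1, Map1a and Grik3 (0.0464 each) with robust spread, Fosb with no filter on low values (0.0426) or without WT 3 (0.0175), and Junb without WT 3 (0.0179).

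At 4 h, 10 of the 32 lists passed camera's test, 2 higher and 8 lower. Immediate early genes stood out most: 20 of 23 members had negative fold changes, with a median of -0.49. Over all genes 3 members passed, and 15 were lower when adjusted over the list alone, among them Nr4a1, Egr1, Fos and Fosb (-1.01 ± 0.19). The list had adjusted p = 1.5e-08, and adjusted p = 0.304 with an estimated correlation. Its score differed by -0.40 between the groups, which do not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. No list at 4 h passed with an estimated correlation or by fry's test of direction, and other splits of the same 6 libraries gave up to 11 lists.

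Endothelial, matrix, meningeal and astrocyte lists lay lower in KO-labelled slices at 4 h. Of 20 endothelial and pericyte markers, 19 had negative fold changes (median -0.33, adjusted p = 6.2e-07, and adjusted p = 0.304 with an estimated correlation). Adjusted over the list alone 5 were lower, and 0 over all genes: examples are Rgs5 (-0.37 ± 0.09), a pericyte regulator of G protein signalling, Cdh5 (-0.33 ± 0.09), the endothelial cadherin, Flt1 (-0.32 ± 0.09) and Tek (-0.53 ± 0.16), receptors for vascular growth factors. Of 45 collagens and matrix glycoproteins, 40 were negative (median -0.23, adjusted p = 1.99e-08, and adjusted p = 0.358 with an estimated correlation); 5 were lower adjusted over the list alone and 0 over all genes, with Sparc at -0.31 ± 0.07, Fbln2 at -0.41 ± 0.10, the fibronectin gene Fn1 at -0.39 ± 0.11 and the basement membrane gene Nid1 at -0.35 ± 0.10. Meningeal markers had 16 of 18 negative (median -0.37, adjusted p = 0.000221, and adjusted p = 0.456 with an estimated correlation). Adjusted over the list alone 4 were lower, and 0 over all genes, led by Ogn, a small matrix proteoglycan, and Foxc1 (-0.67 ± 0.21), a factor of meningeal development. All 17 astrocyte markers were negative (median -0.19, adjusted p = 0.000221, and adjusted p = 0.304 with an estimated correlation), 2 of them lower adjusted over the list alone and 0 over all genes: the glutamate transporter gene Slc1a3 (-0.22 ± 0.06) and the connexin gene Gja1 (-0.26 ± 0.07).

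Choroid plexus and ependymal markers at 4 h had 10 of 12 members negative (median -0.41, adjusted p = 0.000525, and adjusted p = 0.334 with an estimated correlation). Cilia genes made up the 3 that were lower adjusted over the list alone (0 over all genes): Foxj1 (-0.56 ± 0.12), Rsph1 (-0.81 ± 0.20) and Dynlrb2 (-0.78 ± 0.19). Cell cycle genes had 24 of 26 negative (median -0.19, adjusted p = 0.000295, and adjusted p = 0.562 with an estimated correlation), with 0 lower adjusted over the list alone or over all genes; without KO 1 the list did not pass (adjusted p = 0.129). Proinflammatory genes had 21 of 28 negative (median -0.24, adjusted p = 0.00198, and adjusted p = 0.415 with an estimated correlation), 1 of them, the adhesion molecule gene Vcam1 (-0.37 ± 0.08), lower adjusted over the list alone and 0 over all genes. Without both libraries with Xist reads, the cell cycle and proinflammatory lists gave adjusted p = 0.368 and 0.150.

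The excitatory neuron and pan-neuronal lists lay higher at 4 h. Of 20 excitatory neuron markers, 18 had positive fold changes (median 0.25, adjusted p = 0.000221, and adjusted p = 0.304 with an estimated correlation), 7 of them higher adjusted over the list alone and 0 over all genes: Tbr1 (0.46 ± 0.09), Slc17a7 (0.45 ± 0.11) and Neurod2 (0.39 ± 0.08), a neuronal differentiation factor, were among the members with the smallest p. Pan-neuronal and synaptic genes had 21 of 24 positive (median 0.12, adjusted p = 0.000953, and adjusted p = 0.304 with an estimated correlation), with 0 past the threshold either way and the neuronal tubulin Tubb3 at 0.22 ± 0.07. Inhibitory neuron markers had a median of -0.04 (adjusted p = 0.415), and striatal, thalamic and hippocampal markers did not pass either. The differences in endothelial, meningeal, astrocyte, excitatory and pan-neuronal lists stood in the same 6 libraries as the lower immediate early genes.

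Hyaluronan binding and turnover genes, the group closest to TSG-6, did not pass at 4 h: 20 of 26 were negative (median -0.16, adjusted p = 0.0523, and adjusted p = 0.304 with an estimated correlation). Itih2, which encodes a heavy chain of inter-alpha-inhibitor, was lower adjusted over the list alone (-1.13 ± 0.29, 79.8 ± 10.1 in WT and 38.8 ± 20.2 in KO-labelled slices, SD, n = 3 each) and 0 members passed over all genes. The hyaluronan synthase gene Has2 had -0.53 ± 0.22, Ptx3, a TSG-6 partner in hyaluronan matrix, -0.40 ± 0.15, and the brain proteoglycan gene Bcan -0.23 ± 0.09. The list passed without WT 2 (adjusted p = 0.0234) or KO 2 (adjusted p = 0.0414).

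The remaining lists did not pass at 4 h with all 6 libraries. Median log2 fold changes were -0.21 for A2 and -0.19 for A1 reactive astrocyte genes, -0.14 for pan-reactive astrocyte genes (blocked adjusted p = 0.0428), -0.12 for matrix proteases, -0.15 for oligodendrocyte precursor markers, -0.17 for mitochondrially encoded genes, -0.06 for ribosomal protein genes (blocked adjusted p = 0.0472) and -0.10 for TGF-beta and SRF targets, with adjusted p between 0.0523 and 0.0957. Interferon genes (-0.10), microglia (-0.05), myelin (-0.06), striatal (-0.08) and erythroid markers (-0.18), hippocampal (0.08) and thalamic markers (-0.00), hypoxia (0.03), heat shock (-0.02), apoptosis (0.00) and sex-linked genes (-0.33) had adjusted p between 0.231 and 0.892. For hypoxia and apoptosis genes the test pointed down although the medians were not negative. Apoptosis genes passed fry's test for change in either direction (adjusted p = 5.36e-05), as did 7 more lists, and 11 of 22 lay on each side. Leaving out 1 library let 11 of these lists pass at the preset correlation, each pointing lower. With all 6 libraries no list passed with an estimated correlation. Interferon genes passed without WT 3 (median -0.36, adjusted p = 0.000368) or KO 1 (0.0273), A1 astrocyte genes without the same 2 (0.00352 and 0.0408), and microglia markers without WT 2 (median -0.23, adjusted p = 0.00213). Mitochondrially encoded genes passed without KO 3 (0.00136) or KO 1 (0.0470), oligodendrocyte precursor markers without KO 3 (0.00614) or WT 2 (0.0111), and striatal markers without WT 3 (median -0.19, adjusted p = 0.00559). Ribosomal protein genes passed without KO 2, WT 1 or WT 3 (0.00279 to 0.00940), A2 genes without KO 2 or WT 1 (0.0130 and 0.0382) and pan-reactive genes without KO 3 or WT 1 (0.0225 and 0.0391). Matrix proteases passed without WT 1 or WT 3 (0.0354 and 0.0397) and erythroid markers without KO 2 (0.0235).

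The second comparison asks whether KO-labelled and Het slices differed at 24 h in females. No gene passed in edgeR, the smallest adjusted p being 1.00; 657 genes had an unadjusted p under 0.05 against 801 by chance, and DESeq2 called 2. The 5 genes with the smallest p at a mean log2 CPM of at least 1 did not pass either. Lama5, a laminin chain, was 21.9 ± 0.719 CPM in Het (SD, n = 3) and 30.0 ± 1.85 in KO-labelled females (n = 4), a log2 difference of 0.46 ± 0.10. The clock gene Per1 was 92.7 ± 6.62 and 118 ± 8.80 CPM (0.35 ± 0.08), and Sp8, a factor of olfactory interneurons, 12.8 ± 1.11 and 6.91 ± 1.71 (-0.88 ± 0.21). Slfn9 had -0.84 ± 0.21 and the kinase gene Dgkg -0.46 ± 0.12. The genes called by DESeq2, Eif2s3y and Myot, were chosen after their values were seen. Eif2s3y is Y-linked, and 1 library labelled KO female carried Y-linked reads.

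In lists, 10 passed in females, 7 higher and 3 lower, a number that 20 of the 35 splits of these libraries into groups of 3 and 4 reached, with up to 17. All 26 cell cycle genes were negative (median -0.35, adjusted p = 2.44e-12, and adjusted p = 0.68 with an estimated correlation; 0 adjusted over the list alone and 0 over all genes), including Bub1 (-0.57 ± 0.19), a mitotic checkpoint kinase, Rrm2 (-0.47 ± 0.16) and Mki67 (-0.56 ± 0.20). Immediate early genes were positive in 22 of 23 (median 0.45, adjusted p = 1.06e-07, and adjusted p = 0.68 with an estimated correlation; 0 adjusted over the list alone and 0 over all genes), with Junb at 0.77 ± 0.22 and Arc at 1.07 ± 0.38. Choroid plexus and ependymal markers were positive in 15 of 17 (median 0.49, adjusted p = 0.00201, and adjusted p = 0.68 with an estimated correlation). Adjusted over the list alone 8 were higher, and 0 over all genes; they were led by Aqp1, Clic6, Folr1 and Ttr, and 2 KO-labelled female libraries held nearly all the Ttr reads. Without KO female 3 this list had adjusted p = 0.970. Collagens and matrix glycoproteins (34 of 45 positive, median 0.11; 1 higher adjusted over the list alone, 0 over all genes), matrix proteases (25 of 34, 0.09), hypoxia genes (19 of 25, 0.06), heat shock genes (15 of 20, 0.08; Hspb1 0.78 ± 0.25) and A2 astrocyte genes (10 of 11, 0.25) lay higher, and striatal (11 of 15 negative, -0.21) and inhibitory neuron markers (14 of 19 negative, -0.11; 1 lower adjusted over the list alone, 0 over all genes) lower. Their adjusted p was between 0.00201 and 0.0428, and adjusted p = 0.68 to 0.797 with an estimated correlation. Hypoxia genes did not pass without KO female 3 (adjusted p = 0.343). Collagens did not pass without Het female 3, KO female 1 or KO female 4 (up to 0.106). Proteases, striatal, inhibitory neuron and A2 genes each failed without 4 or 5 of the 7 female libraries (up to 0.483). Without the 2 KO-labelled females that held Ttr reads and KO male 3, the striatal list turned, with a median of 0.01 and a test pointing up (adjusted p = 0.0115), and without KO female 2 as well it was 0.33 (adjusted p = 0.000808).

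The third comparison is the same contrast in males. The zinc finger gene Plagl1, an imprinted regulator of growth, had the smallest p, at 27.1 ± 2.93 CPM in Het (SD, n = 3) and 43.6 ± 2.75 in KO-labelled males (n = 4), a log2 fold change of 0.68 ± 0.11, but did not pass in edgeR (adjusted p = 0.137); DESeq2 called it and no other gene (adjusted p = 8.05e-05). No gene passed in edgeR, 1100 had an unadjusted p under 0.05 against 801 by chance, and a fit to the male libraries alone called 1 gene, lower in KO-labelled males: Ndn (adjusted p = 0.0411), another imprinted gene, chosen after its values were seen. The next smallest p were those of Fabp7, a fatty acid carrier of radial glia and astrocytes (372 ± 49.7 and 274 ± 28.1 CPM, -0.44 ± 0.10), Pmm1 (-0.24 ± 0.05), Per1 (0.35 ± 0.08) and Mdp1 (-0.36 ± 0.09), none of which passed.

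Inflammatory genes had high values in part of the KO-labelled males. All 27 proinflammatory genes were positive (median 0.82, adjusted p = 4.4e-09, and adjusted p = 0.574 with an estimated correlation; 0 adjusted over the list alone and 0 over all genes), with the chemokine gene Cxcl10 at 17.6 ± 9.78 CPM in Het (n = 3) and 66.4 ± 53.5 in KO-labelled males (n = 4). The 4 KO-labelled males had 135, 10.3, 78.2 and 42.1 CPM of Cxcl10. Pan-reactive astrocyte genes were positive in 9 of 13 (median 0.32, adjusted p = 0.00206, and adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone 6 were higher, and 0 over all genes, led by the iron-sequestering lipocalin Lcn2 (3.32 ± 0.89; 9.04 ± 5.49 and 86.3 ± 108), Cxcl10 (1.96 ± 0.54), the metalloreductase gene Steap4 (1.78 ± 0.51) and ceruloplasmin, Cp (1.42 ± 0.41). Without Het male 2 or KO male 1 this list had adjusted p = 0.189 and 0.0567. The proinflammatory list passed without any 1 library, with adjusted p up to 0.00139. Its score did not differ between the male groups by exact permutation (p = 0.257, 35 arrangements), nor did the pan-reactive score (exact permutation p = 0.2). All 35 ribosomal protein genes were negative (median -0.14, adjusted p = 2.96e-08, and adjusted p = 0.574 with an estimated correlation; 0 adjusted over the list alone and 0 over all genes).

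Matrix genes in males were mostly positive: 37 of 45 collagens and matrix glycoproteins (median 0.14, adjusted p = 0.000146, and adjusted p = 0.574 with an estimated correlation), of which the proteoglycan Dcn (1.01 ± 0.27) and Lama5 (0.37 ± 0.10) were higher adjusted over the list alone and 0 over all genes. Hyaluronan genes did not pass as a list in males (median 0.06, adjusted p = 0.157, and 0.0493 without Het male 1), but 4 of its 27 members passed adjusted over the list alone (0 over all genes): Vcan (0.30 ± 0.07, 98.3 ± 7.62 and 121 ± 8.09 CPM), a hyaluronan-binding proteoglycan, Ptx3 (1.83 ± 0.57) and Has2 (0.72 ± 0.23; 8.89 ± 1.72 and 14.5 ± 5.54 CPM) were higher and Bcan (-0.32 ± 0.10) lower. Other lists that passed in males were astrocyte markers (15 of 17 negative, median -0.19; Fabp7 lower adjusted over the list alone, 0 over all genes), microglia markers (18 of 21 negative, -0.17), oligodendrocyte precursor markers (11 of 14 negative, -0.24), immediate early genes (17 of 23 positive, 0.26), A2 astrocyte genes (10 of 11 positive, 0.26), interferon genes (24 of 25 positive, 0.38) and matrix proteases (25 of 34 positive, 0.12; Mmp13 2.67 ± 0.85). Their adjusted p was 0.00206 to 0.044, and adjusted p = 0.574 to 0.726 with an estimated correlation. Without Het male 1 the astrocyte, microglia and oligodendrocyte precursor markers had adjusted p = 0.556, 0.533 and 0.226, and without KO male 1 the last had 0.0848. Each of the other 4 did not pass without 2 to 4 of the 7 male libraries, among them Het male 2 (up to 0.778). Altogether 11 lists passed, 7 higher and 4 lower; 17 of 35 splits of the male libraries gave as many, and up to 19.

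Averaged over the sexes at 24 h, of genes with a mean log2 CPM of at least 1, Lama5 (0.41 ± 0.07), Per1 (0.35 ± 0.06), Fabp7 (-0.35 ± 0.07), the trafficking GTPase gene Arl5a (-0.25 ± 0.06) and Hspg2 (0.35 ± 0.08), which encodes the basement membrane proteoglycan perlecan, had the smallest p. None passed in edgeR (smallest adjusted p = 0.141), which had 1060 genes at an unadjusted p under 0.05 against 801 by chance. DESeq2 called 10 genes: Lama5, Per1, Fabp7, Reln, Plagl1, Prdm12, Myot, 9530051G07Rik, the Y-linked Eif2s3y (log2 fold change 11.66), carried by 1 library labelled KO female, and Ttr (10.55), whose reads came from 3 KO-labelled libraries. Of these, Reln, Prdm12, Myot and 9530051G07Rik were named after their values were seen. The limma-voom fit with quality weights called Lama5 and Per1. Lama5 (ENSMUSG00000015647) lies on chromosome 2 at 180176373 to 180225859, and Arl5a (ENSMUSG00000036093) at 52397951 to 52424901, near Tnfaip6 on the same chromosome. Lama5 was 21.9 ± 0.719 and 24.3 ± 3.97 CPM in Het females and males (n = 3 each) and 30.0 ± 1.85 and 31.3 ± 1.53 in KO-labelled females and males (n = 4 each). Leaving out KO female 3 or Het male 3 gave 1 and 2 calls: Reln in the first case (0.40, adjusted p = 0.0289), Lama5 and Per1 in the second.

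Of the lists, 13 passed in the average, 9 higher and 4 lower; 26 of 100 splits that kept the sexes apart gave as many, and up to 17. Collagens and matrix glycoproteins were positive in 42 of 45 members (median 0.09, adjusted p = 7.3e-07, and adjusted p = 0.548 with an estimated correlation). Lama5, Hspg2, Lamc1 (0.20 ± 0.05) and the fibrillin gene Fbn1 (0.27 ± 0.07) were higher adjusted over the list alone, and 0 over all genes. Immediate early genes were positive in 21 of 23 (median 0.40, adjusted p = 1.54e-07, and adjusted p = 0.548 with an estimated correlation). Adjusted over the list alone 6 were higher, and 0 over all genes, including Junb (0.59 ± 0.16), Nr4a3 (0.89 ± 0.24), Nr4a1 (0.85 ± 0.25) and Egr2 (0.85 ± 0.27). Cell cycle genes were negative in 23 of 26 (median -0.24, adjusted p = 3.56e-08, and adjusted p = 0.548 with an estimated correlation), proinflammatory genes positive in 27 of 27 (0.48, adjusted p = 6.86e-08, and adjusted p = 0.577 with an estimated correlation) and ribosomal protein genes negative in 35 of 35 (-0.07, adjusted p = 2.28e-05, and adjusted p = 0.598 with an estimated correlation). In each of these 3 lists, 0 members passed adjusted over the list alone or over all genes. Pan-reactive (0.25) and A2 astrocyte genes (0.33), matrix proteases (0.08), choroid plexus markers (0.35), excitatory neuron markers (0.09) and TGF-beta and SRF targets (0.10) had positive medians, astrocyte (-0.12) and microglia markers (-0.09) negative ones, with adjusted p = 0.000412 to 0.0347, and adjusted p = 0.548 to 0.598 with an estimated correlation. Without Het male 1 the astrocyte and microglia markers had adjusted p = 0.308 and 0.563. Microglia, TGF-beta, choroid plexus and excitatory genes also failed without others of the 14 libraries. Hyaluronan genes had a median of -0.00 (adjusted p = 0.392).

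**Figure D3:**
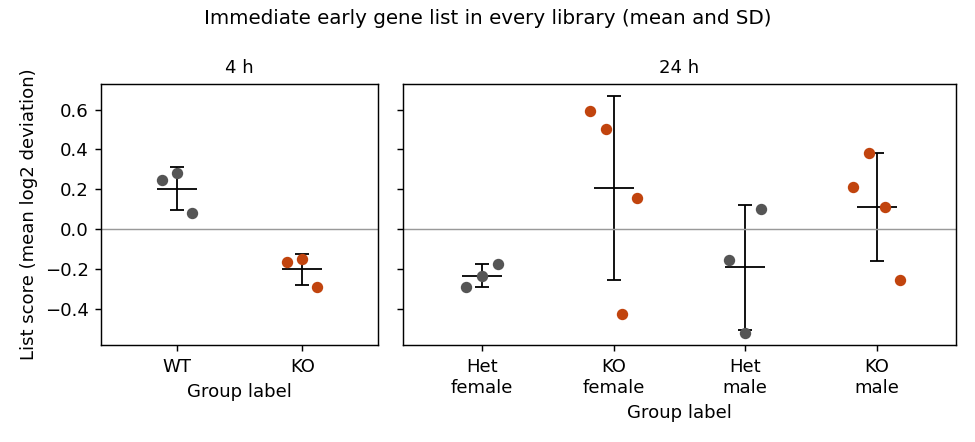
Score of the immediate early gene list (mean log2 deviation of its 23 genes from their means over the libraries of that table) per library at 4 h (left) and 24 h (right), with bars for the mean and SD of each group. At 4 h the 3 KO-labelled libraries lie below the 3 WT libraries; at 24 h KO-labelled and Het libraries overlap.

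The genotype difference was then compared between sexes and between times. No gene passed the test of a difference between the male and female contrasts in edgeR (smallest adjusted p = 0.977; 618 genes at an unadjusted p under 0.05), and DESeq2 called 1, the Y-linked Eif2s3y. No gene was shared by the female and male calls, since edgeR made none. At an unadjusted p under 0.01, 3 genes were higher in both (0.437 by chance, Fisher's exact p = 0.0095) and 2 lower in both (0.188, p = 0.0152). Both contrasts used the same estimate of each gene's spread, so these p-values can overstate the sharing. Across genes, which are not independent, the fold changes of the sexes correlated at a Pearson r of 0.19 (Spearman 0.07), and at a Pearson r of 0.07 over the 13984 genes with a mean log2 CPM of at least 1. The 4 h and 24 h comparisons shared 0 calls, edgeR having made none at 24 h; at an unadjusted p under 0.01 they shared 5 higher genes (2.69 by chance, Fisher's exact p = 0.198) and 0 lower (1.48, p = 0.408), and their fold changes correlated at -0.03 (Spearman 0.07). DESeq2 gave no shared gene in either pair. Time, control genotype and table cannot be told apart in the second pair.

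Males and females at 24 h were compared as a check of the sex labels. Xist, the noncoding RNA of the inactive X chromosome, fell by 8.50 (log2) in males, and the X-linked genes Kdm5c and Eif2s3x, which escape inactivation, fell by 0.34 and 0.52 (edgeR adjusted p = 0.0041, 0.00627 and 0.0147), the only genes past the threshold. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y did not pass, because 1 library labelled female carried them: KO female 2 had 77.1 CPM of Ddx3y and 0 Xist reads, a limit of 0.280 CPM, whereas the other 6 female libraries had 351 ± 11.6 CPM of Xist (SD). Without KO female 2, 9 genes passed. Het male 1 had 107 Xist reads, and the other male libraries 0 to 5. Among the 4 h libraries, for which the labels give no sex, WT 1 (5655 reads) and KO 1 (2355 reads) had Xist reads and the others 0 to 3. Of the lists, 12 passed between the sexes, 7 higher and 5 lower in males, and 1, the sex-linked genes, kept its call with an estimated correlation (adjusted p = 0.0402).

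Reads of Ttr, the transthyretin made by choroid plexus, came from few 24 h libraries: KO female 1 had 19661, KO female 3 had 48186 and KO male 3 had 4922, against at most 8 in any other library. Leaving these 3 libraries out gave 0 genes past the threshold in edgeR in females, males and the average, and leaving out KO female 2 as well gave 0 in females and the average. List calls both ended and arose without the 3 libraries. These are calls at the preset correlation, the only one used in these fits. With all libraries, no genotype list at 24 h passed with an estimated correlation. Those that ended in females were the hypoxia (adjusted p = 0.0797), heat shock (0.0781), A2 astrocyte (0.0610) and inhibitory neuron lists (0.234), in males the interferon list (0.647) and in the average the microglia list (0.559). The striatal list passed in the opposite direction in females, and was higher in the average (adjusted p = 0.00269). Calls also arose for ribosomal (lower, adjusted p = 4.87e-05), endothelial (higher, 0.0306), sex-linked (higher, 0.0129) and thalamic lists (lower, 0.0398) in females. In males they arose for meningeal (higher, 0.00354), myelin (lower, 0.0304) and TGF-beta lists (higher, 0.0446), and in the average for meningeal (higher, 0.00887) and thalamic lists (lower, 0.0124). The cell cycle and immediate early lists passed in females and in the average. Without KO female 2 too, which leaves 1 KO-labelled female, the cell cycle list did not pass in females (adjusted p = 0.350) or in the average (0.300), nor did matrix proteases (0.676 and 0.0947) or A2 astrocyte genes (0.865 and 0.0947). In that setting heat shock (0.751), inhibitory neuron (0.169) and hypoxia genes (0.0502) did not pass in females, nor pan-reactive astrocyte (0.100), excitatory neuron (0.230) and TGF-beta genes (0.343) in the average, where the striatal list was higher (0.000310). Endothelial (higher, 0.0267), erythroid (higher, 0.0475), oligodendrocyte precursor (lower, 0.0339) and thalamic lists (lower, 0.0267) then passed in females, and meningeal (higher, 0.00488), oligodendrocyte precursor (lower, 0.000325) and thalamic lists (lower, 0.00558) in the average. The choroid plexus list did not pass in either setting (0.230 to 0.881).

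**Figure D4:**
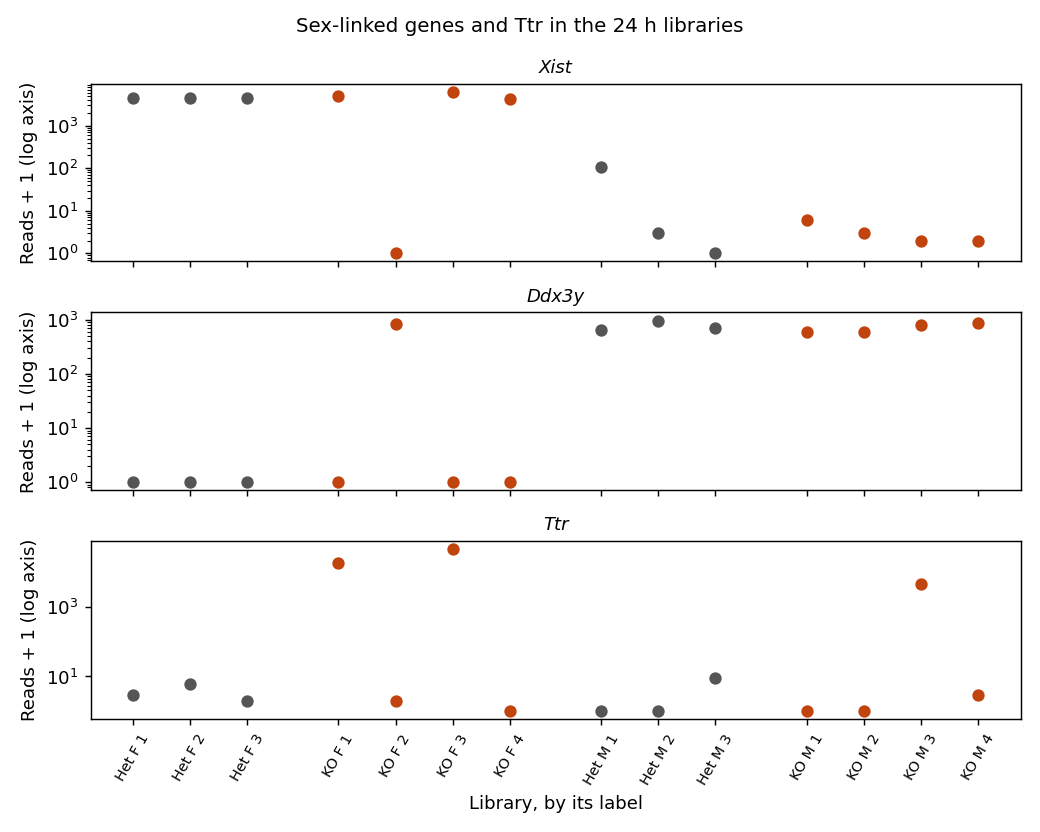
Reads plus 1, on a log axis, of Xist, Ddx3y and Ttr in each of the 14 libraries at 24 h, in order of their labels; grey points are Het and orange points KO-labelled. KO female 2 has the Xist and Ddx3y reads of a male-labelled library, and KO female 1, KO female 3 and KO male 3 hold nearly all Ttr reads.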

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

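The tests of the KO female 2, Ttr and Wdfy1 patterns were chosen after the results were seen. For the count of genes near Wdfy1, the expected outcome was written before the count was made, but Wdfy1 itself was picked from the 4 h results. The tests of other splits and the rules that pick out values were set beforehand.

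Tests for a library far from the rest were run in the KO-labelled females and the KO-labelled males at 24 h, the only groups of 4 libraries. No Het or 4 h library was tested in this way. Each test took 1 gene, list score or read total in 1 group. The tests share libraries and are not independent, so the number given by chance is only a rough guide. Of 123 such tests, 10 flagged a library, where chance gives about 6.15. Of these, 6 belong to KO female 2: Xist (0 CPM), Ddx3y (77.1), Uty (21.2), Kdm5d (29.1), Eif2s3y (26.6) and the sex-linked list score (1.52). A wrong sex label on this library is in line with its Y-linked sum of 154 CPM, which lies 0.312 SD from the mean of the 7 male libraries (151 ± 10.2). Tissue mixed from both sexes is argued against by the limit on Xist, 0.0799% of the level in other females, and a swap with a 24 h male library by the male libraries' own Xist, at most 3.01% of the female level. By the chi-square comparison of counts, the library closest to KO female 2 was KO male 2, at 3.32 per degree of freedom. That was the smallest value of the 82 pairs from different groups. The statistic grows with read depth, however, and KO male 2 had the fewest counts of the 24 h libraries (8482933). KO female 2 lay at 7.86 to 13.6 from the other KO-labelled females. Het female 1 and KO female 4, of unlike genotype label, were nearly as close (3.36), so closeness does not settle a genotype. A wrong label or an animal from outside the series stays open. It could not be settled whether the genotype label of this library is right, since Tnfaip6 does not separate the genotypes.

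The Ttr level of KO male 3 (456 CPM) stood far from the other KO-labelled males. Choroid plexus tissue in these slices is in line with the ratio of Folr1 to Ttr reads in the 3 libraries with over 1000 Ttr reads: 7.68, 9.98 and 7.92 per 1000 in KO female 1, KO female 3 and KO male 3, the highest being 1.30 times the lowest. Kcne2, another choroid plexus gene, varied more and in another order, at 2.64, 1.87 and 3.66 per 1000, from 52, 90 and 18 reads. A rise of Ttr in every KO-labelled slice is argued against by 5 of the 8 KO-labelled libraries, which had no more Ttr reads than the highest Het library. Whether choroid plexus was kept more often in KO-labelled slices cannot be told apart from chance, as 3 of 8 against 0 of 6 libraries gives a Fisher's exact p of 0.209.

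Wdfy1 was higher in KO-labelled slices at 4 h (log2 1.23, 95% interval 1.01 to 1.45). At 24 h the averaged change was 0.09 ± 0.06 and the upper bound of its interval 0.22, below the 4 h interval. A background haplotype carried by the KO-labelled animals of both times cannot be decided from this. The 24 h contrast is with Het libraries, whose animals could carry the same haplotype. On both copies it would hide the difference. On 1 copy it could shrink the difference, by an amount that was not measured. A local haplotype in the 4 h animals stays open: of 51 genes within 5 Mb, 9.80% had an unadjusted p under 0.01, against 4.47% elsewhere (Fisher's exact p = 0.0778), and 0 passed by limma. An effect of the genotype on Wdfy1 at 4 h alone was not tested apart from this.

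Other values far from the rest of their group were the mitochondrially encoded list score of KO female 1 (0.41), Il6 in KO male 1 (15.5 CPM) and the A1 astrocyte list score of KO male 2 (-0.28). In 8 lists the male and female contrasts differed by camera, each with adjusted p = 0.755 with an estimated correlation. The median difference, male minus female, was 0.24 for cell cycle, 0.0702 for chromosome 2 flank, -0.12 for hypoxia, -0.28 for oligodendrocyte precursor, 0.68 for proinflammatory, -0.15 for ribosomal, 0.31 for striatal and -0.10 for heat shock genes. Each of the 8 lost its call without at least 1 library. The proinflammatory difference had adjusted p = 0.429 without KO male 1 and 0.0922 without Het male 2, cell cycle 0.0891 without Het male 3 and ribosomal 0.0506 without Het female 3. Heat shock failed without KO female 2 or Het male 1 (up to 0.146) and striatal without KO female 1, KO female 3 or Het male 3 (up to 0.0908). The oligodendrocyte precursor list failed without 5 of the 14 libraries (up to 0.323), hypoxia without 6 (up to 0.364) and chromosome 2 flank without 8 (up to 0.336).

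Each count was set beside the counts from other splits of the libraries. At 4 h the 10 splits are too few for a share under 0.05: the real split gave 7 genes and the highest other 2, 144 and 14 by DESeq2, 38 and 0 among the 4 splits that part every pair under the block, and 10 and 11 lists. Of these splits, 1 gave as many genes as the real one in each of the first 3 cases, the real one itself, and 6 gave as many lists. At 24 h the real genotype splits gave 0 genes, which every split reaches by definition, so the shares there carry no information. They were 35 of 35 in females, 35 of 35 in males, 100 of 100 in the average and 100 of 100 for the difference between sexes. Other splits gave up to 23, 6, 1 and 58 genes. List counts do not exclude chance: 20 of 35 splits reached the female count of 10, 17 of 35 the male count of 11, 26 of 100 the averaged count of 13, 76 of 100 the count of 8 for the difference between sexes and 23 of 100 the count of 12 between sexes, where the highest other was 20. For the 3 genes that differ between males and females, 1 of 100 splits was as large, the real one itself, and the highest other gave 0. Chance is unlikely there, though 100 splits cannot give a share below 1 of 100.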

How the results depend on the processing

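The fits on recovered reads, other pseudocounts and fits without Xist or Ttr libraries or KO female 2 were chosen after the data were seen; the other alternatives were planned. At 4 h the edgeR test on recovered reads called 7 genes. DESeq2 called 144, robust spread 28, the replicate block 38, a minimum log2 change of 1 left 1, and leaving out both Xist libraries left 1. Leaving out single libraries gave 1 to 211 genes: 1 without WT 1, 2 without WT 2, 4 without KO 3, 11 without KO 1 and 211 without KO 2. At 24 h, without a filter on low counts, edgeR called 180 genes in females, 220 in males, 263 averaged, 165 for the difference between sexes and 215 between sexes. The estimated prior degrees of freedom then went from 6.47 to infinite, so each gene took the trend's spread. DESeq2 called 2, 1, 10, 1 and 6, voom with quality weights 2 averaged and 7 between sexes, and the fit to males alone 1. A minimum log2 change of 1 left 1 gene between sexes.

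At 24 h leaving out single libraries gave 0 to 2 genes averaged (1 without KO female 3, 2 without Het male 3) and 2 to 9 between sexes (9 without KO female 2). The list counts ranged from 6 to 15 in males (6 without KO male 1) and 5 to 14 for the difference between sexes (5 without KO male 1, 13 without KO male 2, 14 without KO female 4). Of the lists that passed with all libraries, 3 of 10 in females, 3 of 11 in males, 8 of 13 averaged, 0 of 8 for the difference and 4 of 12 between sexes passed whichever library was left out. Lists that passed only with a library left out numbered 9 in females, 11 in males, 9 averaged, 15 for the difference and 9 between sexes. In females ribosomal genes were lower without Het female 3 (adjusted p = 0.00339) or KO female 1 (0.000304) but higher without KO female 2 (0.0248). Averaged, interferon genes passed without each of 4 libraries (0.000250 to 0.0311), and oligodendrocyte precursor (0.00845 to 0.0498), mitochondrial (0.00658 to 0.0320) and pan-neuronal lists (0.0116 to 0.0337) without each of 5. The numbers did not pair the 24 h libraries (correlations of -0.109, -0.0374 and -0.117 in females, 0.0867, 0.0298 and 0.0279 in males); the replicate block gave 6 genes in females, 6 averaged and 4 for the difference between sexes, and 13 lists for that difference. The 4 were the Y-linked Ddx3y, Kdm5d, Uty and Eif2s3y, which KO female 2 carried, and the 6 were these with Ttr and Mfrp. The block also ended the calls of collagens in females (adjusted p = 0.134), interferon genes in males (0.317) and microglia markers averaged (0.208). It added 3 lists in females (0.00675 to 0.0292), 4 in males (0.000463 to 0.0203), 3 averaged (0.0157 to 0.0246) and 5 for the difference (0.0128 to 0.0318). At 4 h it added 2 lists, pan-reactive astrocyte and ribosomal genes, and ended no list call. With an estimated correlation or fry's test of direction, 0 lists passed in any comparison but between sexes, where 1 did. At 4 h, 8 lists passed fry's test for change in either direction. At an unadjusted p under 0.01 the 4 h and 24 h comparisons shared 5 genes and the sexes 5.

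Directions reversed for few results. The hyaluronan list in females, -0.04, has a median and a test of opposite sign in some fits; without single libraries its median was -0.0699 to -0.0207, and without the 3 Ttr libraries -0.00535. Without those libraries, Drd2 (0.00634) and the choroid plexus list (0.0154, adjusted p = 0.881) were near 0 in females, and the striatal list, with a median of 0.0140, passed in the opposite direction (adjusted p = 0.0115). Leaving out KO female 2 as well keeps 1 KO-labelled female, assumed to vary like the others; it gave Cemip2 0.0657, Hspa1b -0.0756, Ddit3 -0.0185, Pdyn 0.0325, Rarb 0.175 and Drd2 0.101 in females. List medians were 0.0340 (inhibitory), 0.326 (striatal, again passing upward, adjusted p = 0.000808) and -0.0483 (heat shock), and Nrgn averaged had -0.00946. The cause was not tested. Of results for counts and the targeted gene, 253 values under alternatives stayed the same and 49 moved. Of other results, 4573 kept direction and call, 149 gained a call, 291 lost one and 15 reversed. A result that passed in neither fit counts among the 4573 if its direction held, so that total does not measure how well calls hold. Depth limits low genes: Tnfaip6 rests on 37 to 108 reads per library.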

Other observations

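The test of the immediate early genes across times was chosen after the results were seen, as were the genes named here.

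Single genes at 4 h with negative log2 fold changes were Clk4 (-0.46), a kinase related to Clk1, Wsb1 (-0.54), Ccnl2 (-0.49), Leng8 (-0.58), Pabpn1 (-0.68) and Fnbp4 (-0.42). They were picked from many, and no list that holds them was tested. Without the block and with no other change their limma adjusted p was 0.0900 (Clk4, Wsb1 and Fnbp4) to 0.239 (Leng8). With the replicate block Wsb1 (limma adjusted p = 0.0166), Ccnl2 (0.0390), Leng8 (0.0451), Pabpn1 (0.0475) and Fnbp4 (0.0432) passed. With robust spread Clk4, Wsb1 and Fnbp4 passed (0.0464 each), as did Wsb1 without KO 1 (0.0325). Positive values stood at Lrfn2 (0.62), a synaptic adhesion protein, and Kif21b (0.33), a neuronal kinesin. Their limma adjusted p was 0.0525 and 0.0909, 0.0451 each with the block, and 0.0293 and 0.0464 with robust spread.

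Ptx3, Timp1, Lcn2 and Il6 were spread widely among KO-labelled males at 24 h. KO male 1 had 277 CPM of Ptx3, 135.5 of Timp1, 241 of Lcn2 and 15.5 of Il6, KO male 3 had 81.0, 52.4, 78.6 and 2.32, KO male 4 had 55.1, 36.3, 20.3 and 0.795, and KO male 2 had 27.8, 23.8, 5.22 and 0.356. The 3 Het males lay between 15.9 and 45.9 CPM for Ptx3, 19.3 and 30.6 for Timp1, 3.59 and 14.6 for Lcn2 and 0.684 and 1.36 for Il6.

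A hypothesis is that the immediate early response of KO-labelled slices differs in direction between the times, lower at 4 h and higher at 24 h. The list score was -0.40 (KO-labelled minus WT) at 4 h and 0.37 (KO-labelled minus Het, averaged) at 24 h, a difference of 0.78 with a two-sided exact permutation p of 0.00294 over 24500 arrangements. With the 4 h libraries exchanged only within pairs of the same replicate number, a replicate block added after the result was seen, the exact permutation p was 0.00643 over 9800 arrangements. Both tests exchange labels within each time, so what they test is the absence of a genotype difference at both times. A difference at 1 time alone could also give a small p, so neither test decides whether the direction changed. The pattern was also found and tested on the same data. The control genotype, the table and the time change together, and at 24 h alone the score did not pass (exact permutation p = 0.0514), so an earlier decline, a different control or a different handling of slices may account for it.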
